A study of Achaea janata with 6 samples.

How the data were processed

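Gene expression was measured in the mid-gut of larvae of the castor semilooper, Achaea janata, of the third instar, with a custom Agilent single-colour oligonucleotide microarray. There were 6 arrays in 6 groups, 1 array per group. Per the labels, 1 group fed on normal castor leaf for 12 h (unexposed) and the other 5 fed on leaf carrying a Cry toxin at a dose of 0.170 µg/cm2 for 12, 24, 36, 48 or 60 h. The labels mention feeding in triplicate, but each group has 1 array, and whether its RNA was pooled is not given in the sources used here.

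Each array held 62976 spots, of which 1319 were controls and 61657 carried 57986 probes of 60 bases, 1 probe per transcript. Transcripts and their annotation text are those of the array design, which was built on separate assemblies of control larvae (26923 transcripts) and treated larvae (31063 transcripts), going by the prefix of each transcript name. Of these probes, 3671 were spotted 2 times, and 4221 sequences stood on 2 probes, so that the same gene can appear under 2 transcript names. No genome was used, so no genomic position is given. An annotation other than unknown, uncharacterised, hypothetical or predicted was present for 13386 of the transcripts analysed.

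The scanner files hold spot intensity on a linear scale, background-subtracted and spatially detrended with Feature Extraction 11.5.1.1 (protocol GE1_1105_Oct12), per the file headers, and not scaled between arrays. The authors also deposited a table of log2 values. Its scale and centring are not stated, and were worked out by setting each column against the scanner values: it holds log2 of the processed signal with each column centred near its 75th percentile. Its column medians were −3.48 (unexposed), −3.67 (12 h), −3.60 (24 h), −3.74 (36 h), −3.56 (48 h) and −3.71 (60 h). The 2 records disagree on which array belongs to which label for 4 of the 6 arrays. The scanner files, each tied to its sample by the deposit, were used for the main values, and the labels of the value table were carried through as an alternative fixed in advance and are printed beside them. Which record is right was not decided.

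Control spots and spots marked as non-uniformity outliers were left out, which removed 23 transcripts and left 57963. Levels were log2 of the processed signal minus log2 of the array's 75th percentile, with spots of 1 probe averaged. A transcript not well above background on an array (the Feature Extraction flag) was set no lower than the lowest level well above background on that array, so that a difference against it is a bound, written "at least". No spot was saturated. Of the transcripts, 37962 were well above background on at least 1 array and 22707 on all 6.

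With 1 array per group a difference between an exposed array and the unexposed array has no replicate check and carries no p. Transcripts were counted at 2-fold or more among those well above background on at least 1 of the compared arrays. For each of the 6 arrays, the transcripts at least 2-fold above or below all of the other 5 were counted. Counts shared by all 5 times were set beside the mean of 20 simulations in which 6 unchanged arrays were drawn around each transcript's mean with its SD over the 5 exposed arrays, and beside the overlap of independent lists. Simulated levels were not held to the background flag that the real counts required. The same simulation was run for the 5 arrays left without the array filed as 24 h. The 48 and 60 h arrays, whose labels agree in both records, were also compared with both arrays that a record calls unexposed. That comparison was added after the disagreement was seen.

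Gene lists (29, of which 6 hold markers of other tissues or of plant material) were patterns in the annotation text, fixed before the data were examined. List members are transcripts, so that a gene under 2 transcript names counts under each. The lists of cytosolic ribosomal proteins, respiratory chain, vacuolar ATPase and proteasome were kept as controls. At each time the median log2 difference of a list was given with its percentile among 10000 random lists of annotated transcripts of the same size, matched on mean level in 20 bins. Transcripts well above background on neither compared array were left out of that median. This last filter was added after a first pass, in which floor values of dim transcripts had set several medians, and it raised the number of lists in opposite directions at different times from 4 to 7. Some patterns took in other genes: 4 tetracyclin-resistance transcripts among cell cycle genes, 27 phospholipases among digestive enzymes, 13 inhibitors among serine proteases and 10 mitochondrial-type proton-transporting ATP synthase subunits among the vacuolar ATPase. The list for host plant material holds insect proteins that bind a chlorophyll derivative. Hexamerins also stand in the fat body list. The respiratory chain pattern takes ATP synthase too, so that this list and the vacuolar ATPase list can share those subunits. The test of other tissues on the array filed as 24 h was revised after its values were seen. It first took the excess of the level of each list over each other array (at most 0.188, for cuticle proteins), and all listed tissues were argued against. It was then made member by member, in place of levels of whole lists, with cuticle apart from the other 4 tissues. Fat body was set apart last, once its interval was seen to keep the 4 together from being argued against.

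The 1 test across transcripts was a linear trend over hours of exposure in the 5 exposed arrays, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05) on transcripts well above background on at least 3 of them. Lists were tested on that fit with camera, with a preset correlation between genes of 0.01 and with an estimated one. Departures from a straight line stand in for the missing replicate spread. All 60 orders of the 5 arrays, mirror images counted as 1, were also fitted. Other computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

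Both procedures were tested on simulated data, with 200 transcripts altered at each size. Counting at 2-fold between simulated copies of the unexposed array, over 14373 transcripts, recovered 5% of planted 1.5-fold, 46.5% of 2-fold and all of 4-fold and 8-fold differences. The trend test, over 28815 transcripts, recovered 73% of planted slopes of 2 log2 units per 12 h and 0% of slopes of 1 or 0.5.

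Named transcripts followed a rule fixed before the data were examined: the annotated transcripts highest and lowest at all 5 times, at each time, in the trend and in each list, with those of the added comparison chosen by its gap. Which of the names within that rule the text prints was chosen after values had been seen. Alternatives were normexp background correction (offset 50) on raw spot and background signals, quantile and median scaling, the value table, stricter and no filters on dim probes, thresholds of 1.5-fold and 4-fold, and, for the trend, the row of the array on the slide as a block, each time left out, the unexposed array at 0 h, log2 of hours and a robust variance prior. One transcript per probe sequence, and leaving out the array filed as 24 h, were added after the data were seen.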

Results

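The array filed as 24 h was the dimmest of the 6. The 75th percentile of the processed signal was 102 on the array filed as unexposed, 112 at 12 h, 71.5 at 24 h, 109 at 36 h, 122 at 48 h and 114 at 60 h. Between 47.1% and 56.0% of spots were well above background. Duplicate spots of a probe had an SD of 0.157 to 0.213 log2 units, and 0.469% to 1.16% of duplicate pairs lay 2-fold apart. This spread is technical, within an array. There were no replicate arrays, so that no difference between an exposed and the unexposed array below has a replicate check.

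The deposited records disagree on the labels of 4 arrays. The value-table columns for 48 and 60 h matched their own scanner files. The column called unexposed matched the scanner file of 24 h, the 24 h column matched the scanner file of the unexposed sample, the 12 h column matched that of 36 h, and the 36 h column matched that of 12 h, each with a correlation of 1.0 across transcripts. At least 99.9965% of values agreed within 0.05 log2 units with the matched file, against 4.13% to 5.31% with the sample's own file for these 4 columns. Values below follow the labels of the scanner files unless the value table is named. Because the record moves the unexposed array itself, directions against it turn with the record for many genes. Row 1 of the slide held, in columns 1 to 4, the arrays filed as 24 h, 36 h, unexposed and 12 h. Row 2 held those filed as 48 and 60 h. By the value-table labels this reads unexposed, 12, 24, 36, 48 and 60 h, the order of the times. Place on the slide was not used to decide which record is right.

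**Figure D1:**
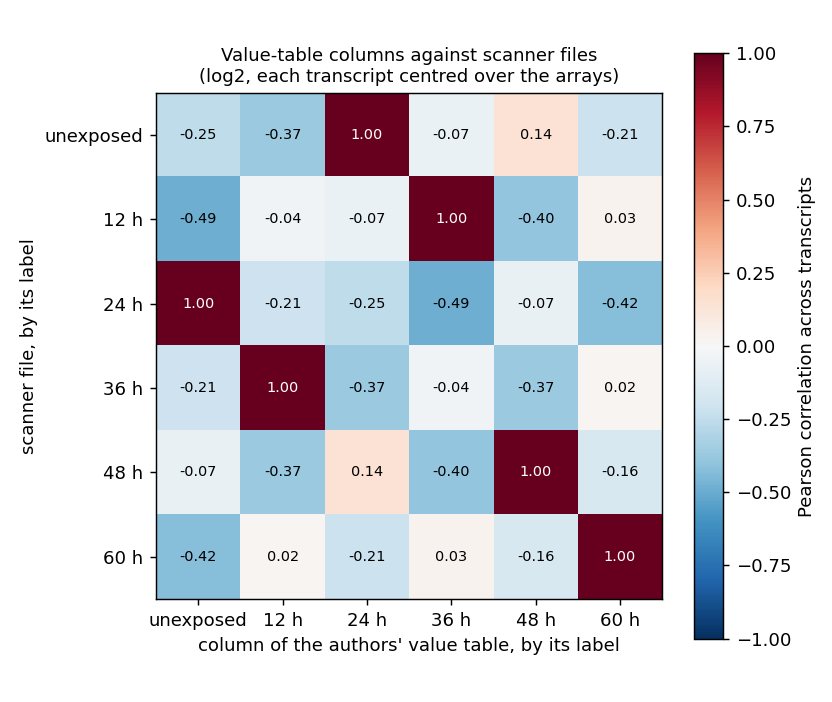
Pearson correlation across transcripts between each column of the authors' value table (x axis, by its label) and each scanner file (y axis, by its label), on log2 values centred per transcript over the 6 arrays. The cells at 1 lie on the diagonal for 48 h and 60 h and off it for the other 4 labels.

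The comparison least open to this disagreement set the 48 and 60 h arrays against both arrays called unexposed by a record. By either record 1 of these 2 is a 24 h exposed array, so that differences already reached at 24 h are left out. The late larvae had also fed for longer than the unexposed ones, which cannot be told apart from exposure. Digestive proteases were among the transcripts higher on both late arrays than on both arrays called unexposed. Trypsin T6 (Treated_c13920_g1_i1) was at least 10.2-fold higher, a trypsin (Control_c26163_g1_i1) at least 9.04-fold, a chymotrypsin-like serine protease (Treated_c12588_g1_i1) at least 11.2-fold and carboxypeptidase B (Control_c16225_g2_i3) at least 14.7-fold, each fold being the smallest of the 4 gaps. The detoxification enzyme cytochrome P450 CYP6AB12 (Control_c15379_g2_i1) was at least 12.8-fold higher, a UDP-glucosyltransferase (Treated_c15607_g1_i1) at least 10.5-fold, fatty acid-binding protein 2 (Control_c9312_g1_i1) at least 10.8-fold, delta-9 desaturase (Treated_c9740_g1_i1), which introduces a double bond into fatty acids, at least 11.6-fold, and Moling (Treated_c18867_g1_i1) at least 40.2-fold. Lower on both late arrays were serine protease 3 (Treated_c18568_g1_i1), by at least 119-fold, UDP-glycosyltransferase UGT42C1 (Control_c18977_g1_i2), by at least 18.8-fold, carboxyl/choline esterase CCE006c (Control_c14358_g1_i1), by at least 5.54-fold, lysozyme-like protein 1 (Control_c27653_g1_i1), by at least 5.12-fold, small heat shock protein G8 (Treated_c12100_g1_i1), by at least 4.55-fold, and glutathione S-transferase epsilon 2 (Control_c14832_g1_i1), by at least 3.98-fold. Alcohol dehydrogenase (Control_c10902_g1_i1) was lower by at least 6.60-fold, hydroxybutyrate dehydrogenase (Treated_c18417_g1_i2) by at least 5.23-fold and regucalcin (Control_c15395_g1_i1), a calcium-binding protein, by at least 3.64-fold.

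In all, 225 transcripts (87 annotated) were at least 2-fold higher on both late arrays and 343 (93 annotated) lower. Of the digestive serine proteases 11 were higher and 3 lower, of the other digestive enzymes 3 and 6, of the detoxification enzymes other than P450 9 and 13, of the peritrophic matrix and chitin transcripts 4 and 5, of immune recognition transcripts 4 and 2, and of heat shock proteins and chaperones 0 and 4. Of the 45 ways to set 2 arrays against 2 others, 35 gave as many transcripts as this one, and the highest gave 1734, so that the total does not mark the late arrays out. The late arrays also lay in row 2 of the slide and the others in row 1, so that row and late exposure cannot be told apart here.

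**Figure D2:**
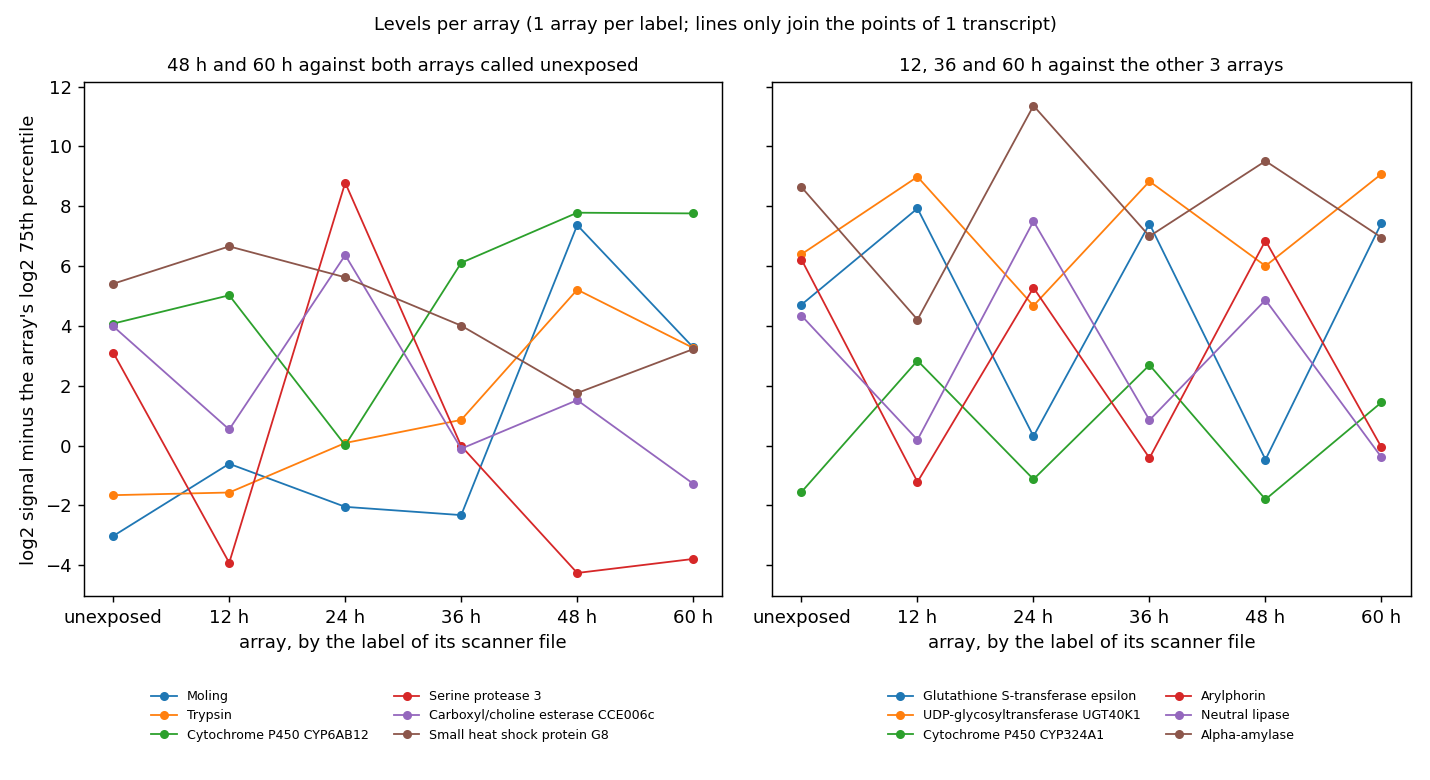
Level on each array (y axis, log2 signal minus the array's log2 75th percentile) against the label of its scanner file (x axis), for 6 transcripts that parted the 48 and 60 h arrays from both arrays called unexposed (left) and 6 that parted the 12, 36 and 60 h arrays from the other 3 (right). Points are single arrays, lines only join the points of 1 transcript, and points of serine protease 3 at 12, 48 and 60 h were not well above background.

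Exposed larvae at each time were compared with the same unexposed array to see which mid-gut transcripts differed during feeding on the toxin. Per the labels, the unexposed larvae had fed only as long as the group of the shortest exposure. At the later times exposure therefore cannot be told apart from longer feeding or larval age. The sets shared by all 5 times, and means over them, carry the same limit under either record. By the labels of the scanner files, 9 of 202 digestive serine proteases were higher on all 5 exposed arrays and 3 lower, and of 94 Cry receptor candidates 2 were higher and 0 lower. Chymotrypsin (Control_c19432_g1_i1) was higher by 5.29 ± 1.59 log2 units (mean and SD over the 5 times), AiC2 chymotrypsinogen (Control_c12609_g1_i1) by 5.03 ± 1.01, cytochrome CYP6AB14 (Treated_c11863_g1_i1) by 5.42 ± 2.37 and juvenile hormone epoxide hydrolase (Treated_c24201_g1_i1), which degrades juvenile hormone, by 4.14 ± 1.37. ABC transporter ABCC2 (Control_c19430_g1_i1), a known Cry toxin receptor of moths, was higher by 4.31 ± 1.20, a cytokine receptor-like protein (Control_c6478_g1_i1) by 4.24 ± 0.78, fatty acid-binding protein 1 (Control_c11439_g1_i1) by 4.10 ± 1.85 and methionine aminopeptidase 1 (Control_c19153_g1_i3) by 3.95 ± 0.59. Lower at all 5 times, the values being log2 differences, were an odorant binding protein (Treated_c14090_g1_i1, −6.05 ± 1.72), Lopap (Control_c1286_g1_i1, −4.21 ± 1.31), an esterase-like protein (Control_c9435_g1_i1, −4.07 ± 2.20), the actin-severing protein gelsolin (Treated_c18350_g1_i1, −3.73 ± 1.30), CYP9G5 (Treated_c12965_g1_i1, −3.39 ± 1.12), the antibacterial peptide gloverin (Control_c1630_g1_i1, −3.07 ± 1.81) and a Kazal-type proteinase inhibitor (Treated_c16714_g1_i1, −2.78 ± 1.32).

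By the labels of the value table these directions turned or vanished. The difference was −4.08 ± 2.21 for chymotrypsin, −5.57 ± 2.29 for CYP6AB14, −1.31 ± 2.23 for ABCC2 and −0.01 ± 1.90 for methionine aminopeptidase 1, and 2.25 ± 3.08 for the odorant binding protein and 4.06 ± 1.35 for gloverin. Under that record, 9 of 36 antimicrobial peptides and lysozymes were higher at all 5 times and 1 lower. Lysozyme (Treated_c5947_g1_i1) was higher by 7.72 ± 1.08, an antibacterial protein (Treated_c21471_g2_i1) by 7.41 ± 1.85 and Heli-7-tox protein (Treated_c21471_g1_i3) by 7.33 ± 1.46, as were CYP6AB32 (Treated_c17976_g1_i1) by 8.50 ± 0.79 and CYP6AB12 by 6.15 ± 1.65, though of 117 cytochrome P450 transcripts 35 were lower at all 5 times and 9 higher. Of 202 digestive serine proteases 49 were lower at all 5 times and 11 higher, of 94 Cry receptor candidates 21 and 2, and of 161 other digestive enzymes 59 and 2. Log2 differences of these enzymes were −10.29 ± 1.60 for beta-1,3-glucanase (Treated_c9479_g1_i1), −6.36 ± 2.58 for neutral lipase (Control_c16040_g1_i3), −6.30 ± 0.90 for pancreatic lipase 2 (Control_c17639_g1_i1), −6.01 ± 1.57 for alpha amylase (Treated_c2909_g1_i1) and −5.96 ± 1.78 for serine protease 11 (Control_c18285_g3_i1). CYP304F1 (Control_c19605_g1_i1) was also lower there, at −7.92 ± 1.73. By the scanner labels lysozyme was at −3.04 ± 3.41 and beta-1,3-glucanase at 2.14 ± 4.87.

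At single times, by the scanner labels, arylphorin (Control_c17729_g4_i1), a storage protein, stood at −7.43 log2 units at 12 h and UGT40R1 (Control_c21221_g1_i1) at 6.05. At 24 h beta-1,3-glucanase stood at 10.37 and lysozyme at −8.96. At 36 h ribosomal protein S27A (Treated_c15190_g1_i1) stood at −7.84. Moling stood at 10.39 at 48 h, and carbonyl reductase (Control_c19129_g1_i1) at 5.60 at 60 h.

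Transcripts at least 2-fold higher and lower than on the unexposed array numbered 3492 and 3999 at 12 h, 6259 and 4083 at 24 h, 4229 and 4025 at 36 h, 2607 and 2987 at 48 h and 3294 and 3601 at 60 h, of 32425 to 34151 transcripts eligible at each time. With the labels of the value table they numbered 4774 and 6007, 4116 and 6195, 4870 and 6908, 3853 and 6473, and 4554 and 6335. The balance of higher and lower depended on the scaling. Under median scaling by the scanner labels it turned at 12 h (4328 higher, 3398 lower) and 60 h (3978 and 3047). The excess at 24 h shrank (5319 and 4886), while 48 h kept more lower (2379 and 3243). At all 5 times 181 were higher and 384 lower, against 303 and 555 in simulations with no effect and 0.668 and 0.595 for independent lists. The labels of the value table gave 914 higher and 2591 lower, against 123 and 294 simulated and 1.56 and 9.81 for independent lists. These comparisons share 1 unexposed array, and part of any overlap may come from it. The simulated counts are no like-for-like reference, since simulated levels were not held to the background flag and their SD takes in differences between times. That SD includes the array filed as 24 h by the scanner labels, but not by the value table, where that array is the reference. The simulations therefore cannot decide whether exposure shifted more transcripts than expected. The array filed as 24 h, which the value table calls unexposed, lay 2-fold outside the other 5 for 3545 transcripts (2647 above and 898 below). The totals were 565 for the array filed as unexposed, 1357 for 12 h, 830 for 36 h, 714 for 48 h and 716 for 60 h. Without the array filed as 24 h, 250 transcripts were higher and 641 lower at all 4 remaining times, against 330 and 589 in simulations of the same kind, with the same limits.

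Among the gene lists, enzymes of digestion were lower at 12 h and higher at 24 h by the scanner labels. The median of the digestive serine proteases was −0.64 log2 units at 12 h (26 members at least 2-fold higher, 70 lower), 0.64 at 24 h (88 and 48; 1.03 over members well above background on both arrays), −0.26 at 36 h (33 and 63), 0.63 at 48 h (77 and 12) and −0.03 at 60 h (46 and 34), where median scaling turned the sign. The other digestive enzymes (lipases, amylases, carboxypeptidases and glucosidases) had medians of −1.18, 1.31, −0.34, 0.22 and −0.28, with 3 members higher and 77 lower at 12 h and 84 higher and 17 lower at 24 h. Both lists were lower at each of the 5 times by the value table, from −0.13 to −1.43 for serine proteases and from −1.03 to −2.30 for the other digestive enzymes. At 48 h, though, the serine proteases (58 higher, 59 lower) were at −0.13 against −0.19 for all transcripts, at percentile 86.4 among random lists. The percentile among random lists was 0 for both at 12 h and 100 for both at 24 h by the scanner labels.

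Antimicrobial peptides and lysozyme were lower at 4 times and higher at 48 h by the scanner labels, with medians of −0.54, −2.34, −1.71, 0.60 and −0.70 from 12 to 60 h. Normexp gave −0.28, −0.76, −0.59, 0.32 and −0.37. Of 32 members compared at 24 h, 15 were not well above background on that array, so that their differences are bounds. At 24 h 1 member was higher and 25 were lower, and at 48 h 11 were higher and 7 lower, at percentiles 0 and 100 among random lists. The value table put the same list higher at each time, with medians from 0.85 at 12 h to 2.87 at 48 h, where 30 members were higher and 2 lower. Immune recognition and signalling genes had medians of −0.65 at 12 h, −0.22 at 24 h, −0.67 at 36 h, 0.07 at 48 h and −0.28 at 60 h by the scanner labels. Over members well above background on both arrays, which leaves out those lowest on the exposed array, they were −0.41 at 12 h, −0.37 at 24 h and −0.20 at 36 h, where 28 of 92 members were dim on the exposed array. The value at 24 h turned positive, and that at 48 h negative, with normexp. The phenoloxidase cascade, which makes melanin, stood at −0.89 at 24 h (−0.24 over members well above background on both arrays) and 0.87 at 48 h by the scanner labels, and at 0.89 and 1.76 by the value table. The list of the REPAT pathogen-response proteins and arginine kinase, with 11 members measured, stood at −1.34 at 24 h (−0.38 with normexp) and 0.51 at 48 h, and at 1.34 and 1.04 by the value table. Protease inhibitors were lower at each time by the scanner labels, from −0.30 at 12 h (−0.10 over members well above background on both arrays) to −1.16 at 36 h (−1.14), and higher at 24 to 60 h by the value table, up to 1.34 at 48 h.

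Cytochrome P450 genes, which oxidise plant and other foreign compounds, had medians of 0.84 at 24 h (52 higher, 29 lower) and 0.53 at 60 h (47 and 14) by the scanner labels, and −0.84 and −0.09 by the value table. Other detoxification enzymes had a median of 0.61 at 24 h (105 higher, 43 lower), and of −0.60 by the value table. In energy metabolism, at 24 h the vacuolar ATPase, the proton pump that energises the larval mid-gut, was higher by a median of 1.76 (32 members higher, 0 lower), and the mitochondrial respiratory chain by 1.24 (75 and 0), both at percentile 100 among random lists. Quantile normalization gave 1.05 and 0.67. With the value table, where that array is the unexposed one, they were lower at each time, from −1.31 to −1.95 and from −0.96 to −1.57. Proteasome subunits stood at 1.02 at 36 h (30 higher, 2 lower), −0.51 at 24 h and −0.58 at 48 h by the scanner labels. The value table put them at 1.57 at 12 h (51 higher, 0 lower). The vacuolar ATPase, respiratory chain and proteasome were control lists, of which the vacuolar ATPase and respiratory chain can share ATP synthase subunits. Their members moved together, with an estimated correlation in the trend fit of 0.83, 0.75 and 0.94 by the scanner labels. Random lists are drawn without regard to such correlation, so a percentile among them does not gauge the spread between arrays. Cry receptor candidates (aminopeptidase N, cadherin, alkaline phosphatase and ABC transporters) had a median of 0.61 at 24 h (33 higher, 8 lower) and within 0.2 log2 units of 0 at the other times, and were lower at each time by the value table, from −0.39 to −0.87.

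Hexamerins and other storage proteins, made by the fat body, had the widest range of medians: by the scanner labels they were −3.37 at 12 h, 0.26 at 24 h, −1.44 at 36 h, 1.39 at 48 h and −2.35 at 60 h, and by the value table −5.87, −0.25, −6.48, 1.23 and −4.74. At 12 h normexp gave −1.14, members well above background on both arrays gave −6.87, and 5 of 11 members were not well above background on the exposed array. The fat body markers, which include the storage proteins, stood at −1.77, 0.22, −0.70, 0.14 and −0.60 by the scanner labels, and at −2.30, −0.21, −2.09, 0.66 and −2.14 by the value table. Among markers of other tissues, cuticle proteins were at 1.43 at 24 h and 1.0 at 36 h by the scanner labels, where the vacuolar ATPase and respiratory chain were also higher. By the value table cuticle proteins stood at −0.40, −1.27, −1.30, −1.06 and −1.13 from 12 to 60 h. The ranges that follow are by the scanner labels. Muscle markers lay between −0.36 and 0.08, haemocyte markers between −0.38 and 0.09, markers of nervous and enteroendocrine cells between −0.52 and 0.17, and the chlorophyllide-binding proteins of the host plant list between −0.14 and 0.29.

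For the remaining lists, medians of the mean difference over the 5 times are given by the scanner labels and then by the value table. These were 0.09 and −0.20 for antioxidant enzymes, 0.14 and 0.09 for heat shock proteins and chaperones, −0.11 and −0.51 for peritrophic matrix and chitin genes (0.064 without 12 h by the scanner labels), −0.01 and −0.21 for juvenile hormone and ecdysone genes, and 0.06 and 0.52 for apoptosis genes. They were −0.31 and −0.04 for autophagy and lysosome genes, 0.09 and 0.38 for cell cycle and DNA replication genes, 0.05 and −0.08 for growth factor and stem cell signalling genes, and −0.02 and −0.43 for cytosolic ribosomal proteins. Cell cycle genes were lower at 24 h, at −0.41 (4 higher, 31 lower), and 0.41 by the value table. Of the 145 list medians by the scanner labels, 30 changed sign under median scaling, quantile normalization or normexp, the largest of them 0.35 in size. Of the 41 medians of at least 0.5 in size, 30 were smaller by over 1.5 times with normexp, 3 with quantile normalization and 0 with median scaling. Median scaling put the median of all measured transcripts at 0.18 at 12 h, −0.01 at 24 h, 0.17 at 36 h and 0.17 at 60 h, against 0.04, 0.13, 0.10 and 0.05.

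**Figure D3:**
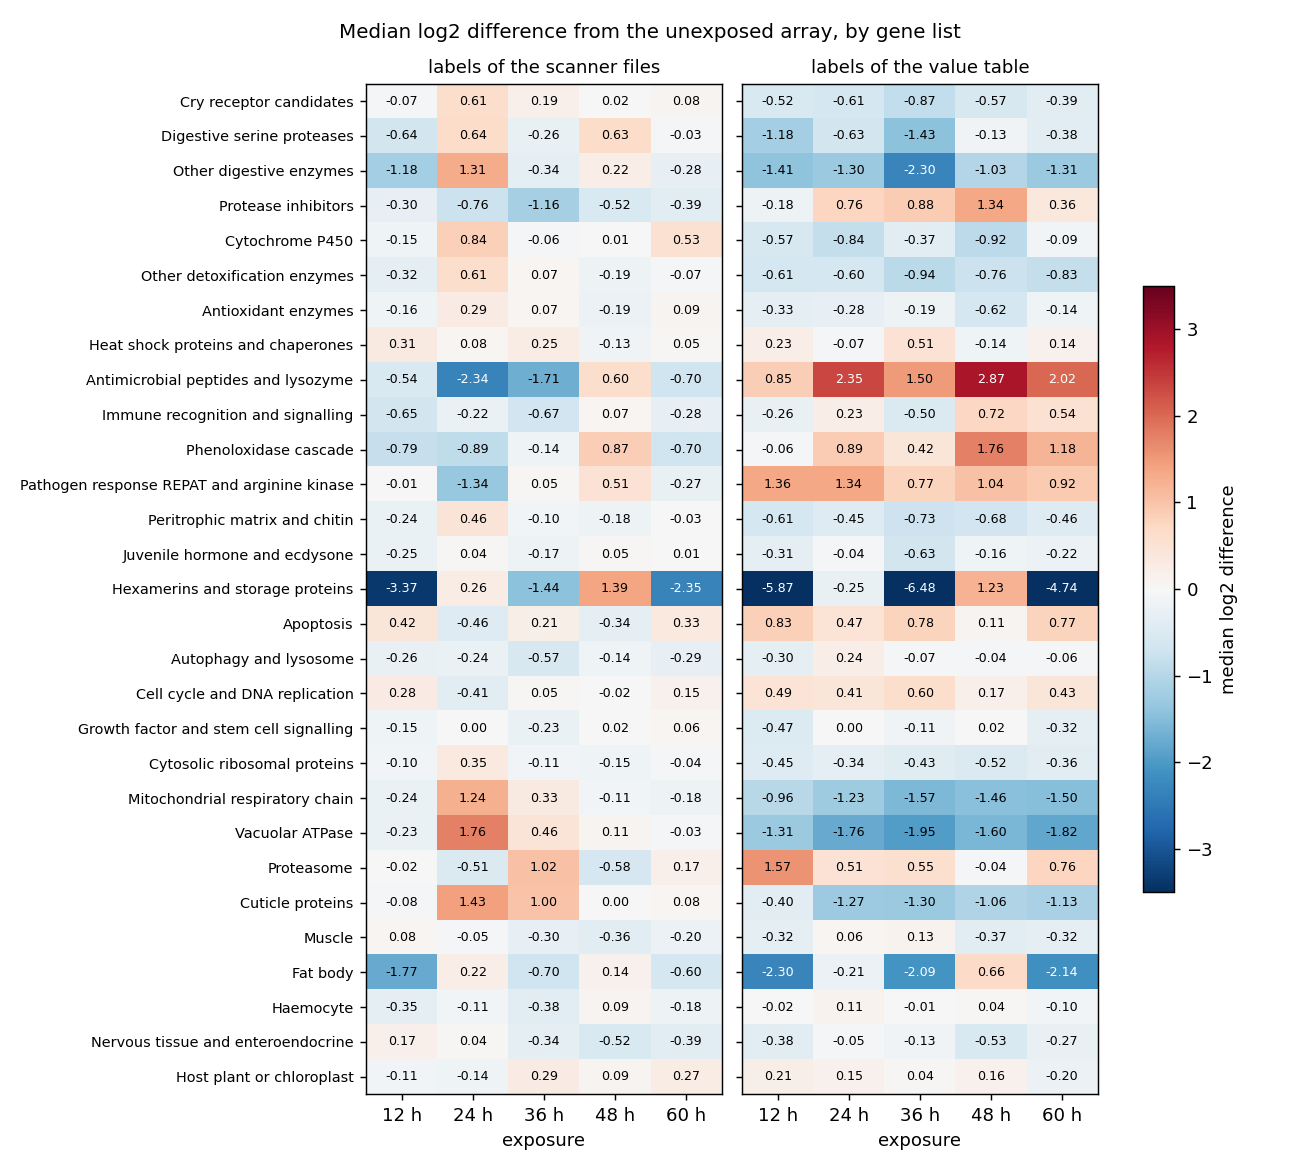
Median log2 difference from the unexposed array (colour and number) for each gene list (rows) at each exposure time (columns), by the labels of the scanner files (left) and of the value table (right). The vacuolar ATPase stands at 1.76 at 24 h on the left and between −1.31 and −1.95 on the right; colours stop at 3.5 either way.

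A linear trend over the hours of exposure was tested in the 5 exposed arrays. Since no unexposed array was fed for 24 to 60 h, hours of exposure cannot be told apart from hours of feeding or larval age. No transcript passed in limma at an adjusted p of 0.05: 0 of 28815 rose and 0 fell, with 466 rising and 515 falling at an unadjusted p under 0.05. With the labels of the value table, 0 of 29481 passed, with 380 and 502 unadjusted. The rising slopes of smallest p, which did not pass (adjusted p = 1.0), were those of the lipid droplet proteins perilipin (Control_c21407_g1_i1), at 0.72 ± 0.12 log2 units per 12 h (SE), and lipid storage droplet-1 (Control_c21892_g1_i1), at 0.73 ± 0.12, and of gloverin (Control_c27340_g1_i1), at 0.83 ± 0.15, serine proteinase-like protein 1 (Treated_c19153_g1_i1), at 1.05 ± 0.20, and immulectin-4 (Treated_c18618_g1_i2), at 0.80 ± 0.15. Gloverin at 24 h, and serine proteinase-like protein 1 at 12 and 24 h, were not well above background and stood at those arrays' floors, so that their slopes and SE rest partly on bounds. The falling ones, which did not pass either, were REPAT30 (Control_c14319_g1_i1), at −0.96 ± 0.13, a pyridoxal phosphate-dependent protein (Treated_c10416_g1_i1), at −0.91 ± 0.13, UGT40M1 (Treated_c18392_g1_i1), at −0.94 ± 0.16, the receptor GPRmth4 (Treated_c23317_g1_i1), at −0.72 ± 0.15, and ribosomal protein S15A (Control_c6643_g1_i1), at −0.96 ± 0.21. In simulations the trend test recovered 0 of 200 planted slopes of 1 and 146 of 200 of 2, so that slopes of this size were not detectable.

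As sets, camera with its preset correlation called antimicrobial peptides and lysozyme upward (adjusted p = 8.73e-07, median slope 0.33), with digestive serine proteases (7.32e-06, 0.18), immune recognition and signalling (4.73e-05, 0.16) and haemocyte markers (0.0483, 0.07). With an estimated correlation these calls were lost, at adjusted p = 0.711, 0.711, 0.655 and 0.655 in the same order. The mitochondrial respiratory chain was called downward (1.74e-05, −0.13), with nervous (0.000493, −0.17) and muscle markers (0.00225, −0.10), heat shock proteins and chaperones (0.0119, −0.05) and the vacuolar ATPase (0.0483, −0.11). These calls were lost too with an estimated correlation, at adjusted p = 0.897, 0.539, 0.655, 0.897 and 0.897. With the value table the preset correlation called antimicrobial peptides (adjusted p = 0.000128), serine proteases (2.58e-07), immune recognition (0.000672), protease inhibitors (0.00367), P450 genes (0.0198) and the phenoloxidase cascade (0.0229) upward and the respiratory chain (1.06e-08) and the proteasome (5.15e-13) downward. None of them held with an estimated correlation, at adjusted p = 0.660 for protease inhibitors and 0.650 for each of the others. The P450, antioxidant and peritrophic lists, which did not pass, had a median slope and a camera direction of opposite sign by the scanner labels. Adjusted over the list alone, 1 falling member of the REPAT list passed, and no member of another list by the scanner labels.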

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

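The tests of other tissues and of a wrong label were chosen after the result was seen; those of lower signal and of the order of the times were set beforehand.

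Medians of 7 of the 29 gene lists stood apart in opposite directions at 2 exposure times by the scanner labels, each at least 0.5 log2 units from 0 and among the outer 2.5% of random lists on its side. With 1 array per time these differences were not tested. The digestive serine proteases differed by 1.28 between 24 h and 12 h, and the other digestive enzymes by 2.49. Antimicrobial peptides and lysozyme differed by 2.95 between 48 h and 24 h, the phenoloxidase cascade by 1.76 and the list of REPAT proteins and arginine kinase by 1.85. Hexamerins and storage proteins differed by 4.76 between 48 h and 12 h, and proteasome subunits, a control list, by 1.60 between 36 h and 48 h. The minimum of 0.5 was kept on both sides by 5 of the 7 lists under median scaling, 6 under quantile normalization and 3 with normexp. Serine proteases missed it under each of these (0.33 at 24 h with quantile normalization), REPAT and arginine kinase under median scaling and normexp, and antimicrobial peptides (0.32 at 48 h) and the proteasome (−0.498 at 48 h) with normexp. The phenoloxidase cascade, which kept it under each scaling, stood at −0.24 at 24 h, short of the minimum, without the 2 of 15 members that were not well above background on that array. By the value-table labels, of the 7 only the hexamerins kept it at the same times.

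Of these 7 differences, 5 involve the array filed as 24 h, which lay outside the other 5 arrays for more transcripts than any other array did. Its lower signal is argued against as the whole cause: among the 7569 transcripts of highest mean level, under quantile normalization, it still lay outside for 682, which is 2.01 times the highest number of another array (340). RNA of muscle, haemocytes or nervous tissue is argued against too: member by member, the smallest median difference of their markers from another array was at most 0.043 log2 units (nervous tissue). Nervous markers were still higher here than at 36, 48 and 60 h (by 0.40, 0.54 and 0.29), and muscle markers than at 36 and 60 h (by 0.34 each). Their 95% intervals were wholly positive, with no such gap from the unexposed and 12 h arrays. RNA of cuticle-forming tissue stays open, since cuticle markers were higher on this array than on each other one, by a median of 0.42 against 36 h (95% interval 0.15 to 0.86) and of over 1 against the rest, as does fat body RNA (−0.65 against 48 h, −1.73 to 0.73). A wrong label stays open, because this array correlates at 1.0 with the column that the value table calls unexposed, and the array filed as unexposed is out of place with it. A response at 24 h of exposure, which the design names, stays open as well and was not tested.

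No transcript passed the trend test over the hours of exposure. With 0 transcripts in the real order, each of the 60 orders (60 of 60) gives as many whatever the data, so that this count says nothing about chance; the highest other order gave 1. At an unadjusted p under 0.05 in limma the real order gave 981 transcripts, 45 orders gave as many and the highest gave 3799. The real order thus did not stand out. In both records the order of the highest count put the 12, 36 and 60 h arrays before the 24 and 48 h ones, the split described under Other observations. Whether that count exceeds what unchanged arrays give was not tested, since no value for unchanged arrays was worked out for it.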

How the results depend on the processing

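Signal over background limits dim transcripts, whose values are bounds. No paired analysis was possible because each group has 1 array. The alternative of the brightest probe per transcript was not run, since each transcript has 1 probe. One transcript per sequence, the late comparison and leaving out the array filed as 24 h were chosen after the data were seen. Of the counts other than those of the trend, 49 stayed within 1.5 times and 79 moved. Of the list medians over the 5 times, 66 of 377 changed sign and 142 more changed in size by over 1.5 times, 17 of 29 with normexp. Of the 377, 348 were classed as the same as the main value, 17 as moved and 12 as reversed. The same meant within 1 SD (over the list's medians at the 5 times), a wide bound, and 179 of the changed ones were so classed. Some classed as reversed also lay within 1 SD, so that 348 is not the count of all values within it. Of the named transcripts, 30 of 366 changed sign (all with the value table) and 33 more changed by over 1.5 times. No trend call appeared in any alternative, the smallest adjusted p ranging from 0.357 (unexposed array at 0 h) to 1, which says nothing about stability, since the test recovered 0 of 200 planted slopes of 1. Quantile and median scaling and 1 transcript per sequence kept the counts other than those of the trend within 1.5 times. The cause of the other moves was not tested, except that filters and thresholds change how many transcripts can be counted.

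Counts are given as higher and lower at 12, 24, 36, 48 and 60 h, at all 5 times, and on the late arrays against both unexposed candidates. Normexp gave 1376 and 1522, 2411 and 1930, 1677 and 1462, 838 and 926, 1205 and 1270, 44 and 106, 73 and 98. Transcripts well above background on all 6 arrays gave 2007 and 2281, 3823 and 2718, 2567 and 2160, 1261 and 1569, 1839 and 2063, 115 and 118, 94 and 201. No filter gave 6203 and 8329, 10966 and 7456, 7350 and 7896, 6473 and 6281, 6210 and 7745, 508 and 924, 499 and 832. The 1.5-fold threshold gave 6828 and 6913, 9715 and 6965, 8382 and 6960, 5830 and 6505, 6845 and 6683, 489 and 895, 721 and 939. The 4-fold threshold gave 962 and 1321, 2159 and 1242, 1079 and 1317, 598 and 716, 919 and 953, 54 and 54, 43 and 48. The value table gave 6007 lower at 12 h, 4116 and 6195 at 24 h, 6908, 6473 and 6335 lower at 36, 48 and 60 h, and 914 and 2591 at all 5 times. Without the array filed as 24 h, 641 were lower at all times.

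Under the value table the list medians over the 5 times reversed to 0.49 for protease inhibitors, −0.32 for P450, 1.98 for antimicrobial peptides, 0.15 for immune recognition, −1.33 for the respiratory chain, −1.71 for the vacuolar ATPase and −1.02 for cuticle proteins. The median of Peritrophic matrix and chitin reversed to 0.037 on all 6 arrays, 0.037 with no filter, 0.064 without 12 h and 0.0057 without 36 h, and the median of Mitochondrial respiratory chain to −0.031 without 24 h.

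Under the value table the mean difference over the 5 times reversed to −3.12 for fatty acid-binding protein 1, −1.21 for AiC2 chymotrypsinogen, 2.41 for Lopap, 4.06 for gloverin, −6.30 for pancreatic lipase 2, −0.0064 for methionine aminopeptidase 1, −1.31 for ABCC2, −4.08 for chymotrypsin, −7.92 for CYP304F1, −3.68 for a chymotrypsin-like protease (Control_c20803_g1_i3), −0.58 for the cytokine receptor-like protein and 4.65 for the esterase-like protein. It reversed to −5.57 for CYP6AB14, 2.17 for CYP9G5, 2.25 for the odorant binding protein, 0.91 for a chemosensory protein (Treated_c14480_g1_i1), 5.29 for a metalloendopeptidase (Treated_c15073_g1_i1), 0.49 for the Kazal-type inhibitor, 1.07 for gelsolin, 0.88 for hydroxybutyrate dehydrogenase, −6.36 for CYP324A6 (Treated_c18993_g1_i2), 7.33 for Heli-7-tox protein, 7.41 for the antibacterial protein, 0.50 for a short-chain dehydrogenase (Treated_c22322_g1_i1), −0.96 for juvenile hormone epoxide hydrolase, 7.72 for lysozyme and −10.29 for beta-1,3-glucanase.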

Other observations

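The alternation described here was noticed in the data and its names were chosen after their values were seen; the count of other splits was set after that, and the clock gene, spike-in and apolipophorin tests beforehand, though how their values were to be read was settled after they were seen and the count of clock genes by name was added then. Over all 6 arrays, 337 transcripts parted the 12, 36 and 60 h arrays from the unexposed, 24 and 48 h arrays by at least 2-fold between the nearest arrays, more than any of the other ways to part them 3 against 3, of which the next gave 270. Both records put the same arrays on each side. Higher on the 12, 36 and 60 h arrays were 125 transcripts (50 annotated), among them enzymes that conjugate foreign compounds (folds are between the nearest arrays). These were a glutathione S-transferase epsilon by at least 6.51-fold, microsomal glutathione transferase by at least 9.54-fold (3.04-fold for another entry), UGT40D2 by at least 6.02-fold (3.06-fold for another entry) and UGT40K1 by at least 5.41-fold. The P450 CYP324A1 was higher by at least 5.94-fold. Gamma-glutamylcysteine ligase, which starts the synthesis of glutathione, was higher by at least 2.84-fold. Juvenile hormone diol kinase was higher by at least 2.72-fold and a heat shock cognate 70 protein by at least 2.53-fold.

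Lower on those arrays were 212 transcripts (92 annotated), among them storage proteins and enzymes of digestion. Arylphorin (Control_c17729_g4_i1) was lower by at least 40.4-fold, neutral lipase (Control_c14410_g1_i1) by at least 11.3-fold and carboxylesterase ae17 (Treated_c23393_g1_i1) by at least 6.93-fold. Alpha-amylase (Treated_c19191_g1_i1) was lower by at least 3.12-fold and a chymotrypsin-like serine protease (Treated_c18343_g1_i1) by at least 3.79-fold. Each is the largest among several entries of that name past 2-fold. The smallest was 2.49-fold for arylphorin, 2.52-fold for neutral lipase and 2.12-fold for carboxylesterase ae17. In contrast, a chymotrypsin (Treated_c16821_g1_i1) was higher by at least 2.35-fold and trypsin Hz3 (Treated_c11901_g1_i1) by at least 2.14-fold. By list, counted as transcripts, 5 digestive serine proteases were lower and 3 higher, 16 of the other digestive enzymes were lower and 2 higher, 6 hexamerin transcripts lower and 0 higher, and 8 P450 transcripts higher and 2 lower, while the detoxification enzymes other than P450 ran 11 each way. The median over the proteasome list was 0.78 log2 units higher, with no member past 2-fold between the nearest arrays.

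Among the 5 exposed arrays alone, 886 transcripts parted 12, 36 and 60 h from 24 and 48 h, and the highest of the other splits gave 619 (846 and 647 by the value table). This was 1 of 10 splits, too few for a share under 0.05. Odd slide columns held the unexposed, 24 and 48 h arrays and even columns the 12, 36 and 60 h arrays, so that column and set coincide. A position effect of the column is argued against, for probes well above background, by the spike-in probes added to the labelling. Their median absolute difference between odd and even columns was 0.0248 log2 units (7 probes, each averaged over its spots) against 0.377 for transcripts. Handling of RNA before the labelling was not tested. A candidate explanation is the time of day at collection, since alternate times lie 24 h apart: of the clock gene transcripts, 22.2% (4 of 18, exact 95% interval 6.41% to 47.6%) were parted, against 29.2% of all transcripts and 20% by chance. The rule set beforehand asked for at least 50%, and took a share no higher than that of all transcripts as against it. The share is lower, but the list also held takeout and takeout-like transcripts, some annotated as juvenile hormone binding proteins. The parted ones were all cryptochromes or PAR-domain protein 1, so the takeout entries lower the share. Several transcripts are also of 1 gene. By gene name, takeout-like names included, 30% (3 of 10, 6.67% to 65.2%) were parted, an interval that excludes neither, which leaves time of day open. Against it, the labels give the unexposed larvae 12 h of feeding, the same as the 12 h group, yet the array called unexposed by either record lies with 24 and 48 h; whether feeding started at the same time of day is not given in the sources used here. Fat body RNA stays open too, since apolipophorin transcripts ran both ways (median −0.333, from −4.50 to 1.28, 7 transcripts). That median is smaller than the 0.5 set beforehand to argue against it. It is, though, the value of 1 transcript (Treated_c9712_g1_i1) near the background floor, with levels from −3.92 to −3.07 on the 6 arrays.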
